A study of Mus musculus with 10 samples.

How the data were processed

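Open chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, with the Omni-ATAC variant and Nextera library reagents at 55 ng of input, per the labels' protocols. The 10 libraries fall into 5 groups of 2: mouse satellite cells sorted from hindlimb muscle and used at once, primary myoblasts grown from such cells and used between passage 5 and 15, and in vitro derived satellite cells (idSCs), the GFP-positive cells of skeletal muscle organoids, taken on day 10, day 20 or day 30. The organoids were seeded from myoblasts, and their medium was exchanged for differentiation medium on day 20 for the last 10 days. The animals carried a transgene that puts a nuclear GFP under Pax7 control (Pax7-nGFP) on the C57BL/6J background, were of either sex and were 2 to 6 months old. Myoblasts were purified on the nuclear GFP or on α7 integrin, and the labels do not say which was used for which library. Nothing in the labels says whether the replicates of a group came from separate animals or cultures.

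Per the submitters' processing notes, bcl2fastq, Bowtie2, Picard, Genrich and SAMtools were used with the mouse build mm10. Versions, settings and the role of each tool are not given in the sources used here, so whether reads were shifted for the Tn5 cut, how duplicates were handled and which filters were applied is unknown. The deposited data were 5 peak lists, 1 per group, in the layout of an irreproducible discovery rate (IDR) comparison of 2 replicates, per the columns of the files. Each list therefore already joins both libraries of its group, and a peak is present only where both libraries had a signal there. The deposited score of a peak is its scaled IDR score, the deposited −log10 value is that of its global IDR, and the deposited signal of a peak is the sum of its values in both libraries, which differed from the sum of the per-library columns by at most 1e-05. The unit of the signal is not stated. No library signal in any list was under 200.002. The lists had not been restricted by IDR: the highest global IDR of a peak was 0.316 in satellite cells, 0.417 in myoblasts and 0.355, 0.589 and 0.437 on days 10, 20 and 30. Scores and signals are the authors' own values, and they were used to rank or filter peaks within a list, to compare the libraries of a list and, centred on the autosomes of each library, to compare chromosomes between groups at regions called in all 5 lists. Which per-library column is replicate 1 is not stated, so they are called library a and library b in the order of the columns. All per-library columns were used. The sequencing depth of the libraries is unknown.

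Peaks on unplaced sequences were left out (33 in satellite cells, 12 in myoblasts, and 18, 30 and 24 on days 10, 20 and 30). The remaining peaks of all 5 lists were merged into union regions where they overlapped by at least 1 bp, and a region was called in a group when a peak of its list overlapped it. Regions were classed as satellite-cell-only (called in satellite cells and not in myoblasts), myoblast-only, or shared, and the share of each class called on each organoid day was computed. A region that is not in a list was not called there, which is not the same as closed. For the class shares as deposited, an exact (Clopper-Pearson) 95% interval, which covers counting error only, and the range over the 19 autosomes were computed. They are printed for the main shares only. Overlap of lists was measured as the Jaccard index in base pairs, with 100 circular shifts of 1 list within each chromosome giving the value of unrelated lists. The calls compared have 1 value per group, so they were not tested between groups and no p-value is given. The signals of the 10 libraries at regions called in all 5 lists were not tested between groups either, since the scaling between libraries is not stated; agreement between the libraries is described by Spearman's rho over the peaks of a list.

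Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the assembly behind mm10. The table gives gene starts and ends without strand or exons. Promoters and introns could therefore not be separated, and the rules fixed before the data were examined were adapted. A gene boundary is the window within 1000 bp of either end of a protein-coding gene. A region was assigned to the nearest protein-coding gene body within 100 kb. Of 75178 union regions, 69065 were assigned to 15741 of 21887 protein-coding genes. The search for transcription factor motifs needs a genome sequence and was not run. Of 454 entries in 23 gene lists fixed beforehand, 453 were matched to the gene table; Mx1 was not.

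For each list, the log2 ratio of satellite-cell-only to myoblast-only regions (with 0.5 added to both counts) and the percentage of its regions called in each group were placed among 10000 random lists. The random lists had the same number of genes, each drawn from the member itself and 100 genes beside it when ordered by number of union regions. Genes with equal numbers stood in alphabetical order. A draw could therefore return the member, other members of its list or genes of the same family with similar names. The simulated data described below were not made to check this. These percentiles describe the lists and are not p-values. With 23 lists and a range of 2.5 to 97.5, chance puts 1.15 lists outside for each of the 13 measures computed, and the measures are not independent. The computations were tested on simulated data. For the class shares, 30000 simulated regions gave back the shares they were made with, to within 0 percentage points. Peaks of neighbouring simulated regions could not touch, so this checked the counting and not the chaining of adjoining peaks. For the gene lists, with 3000 simulated genes and 30 genes per list, the planted list came out at percentile 100, and 2 of 40 random lists lay outside the range.

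Named genes followed a rule set beforehand: 12 fixed myogenic, quiescence and Notch genes; the 10 genes with the largest excess of satellite-cell-only over myoblast-only regions and the 10 with the reverse; the 10 genes each with most satellite-cell-only regions called in any idSC list, most myoblast-only regions not called on day 30, and most regions called on all 3 days in neither reference; and from each list up to 4 members with the largest difference, plus members whose boundary call differed where at most 4 did. Genes with large bodies collect more regions, so excess counts favour them.

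The alternatives were a global IDR of at most 0.01 or 0.05, all lists shortened to 32109 peaks by score or by signal, a reciprocal overlap of 50% or summits within 250 bp, autosomes alone, chromosomes 6, 14, X and Y left out, regions away from gene boundaries, the strongest 25% of a class by signal, boundary windows of 2500 bp and assignment within 50 kb. At equal length by score, ties were ordered by signal; on days 20 and 30 the limit fell among 26803 and 9289 peaks tied at the lowest score, and both rules kept 31320 and 32109 of the 32109 peaks in common, so they are nearly or fully the same there. The strength of satellite-cell-only regions was their signal in satellite cells, and that of myoblast-only regions their signal in myoblasts. Leaving out 1 library was not possible on joint lists. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.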

Results

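Chromatin accessibility was compared between freshly sorted mouse satellite cells, the resident stem cells of skeletal muscle, cultured primary myoblasts, and GFP-positive idSCs recovered from muscle organoids that had been built from myoblasts. The design asks whether organoid culture brings the open chromatin of myoblasts closer to that of satellite cells, and on which day. The satellite cell list held 32109 peaks covering 32.9 Mb and the myoblast list 53738 peaks covering 53.2 Mb. The idSC lists held 45938 peaks on day 10, 54968 on day 20 and 37674 on day 30, covering 50.6 Mb on day 10, 49.7 Mb on day 20 and least on day 30, where peaks had a median width of 932 bp. The share of peaks with a global IDR of at most 0.05 was 69.3% in satellite cells and 52.9% in myoblasts. It was 64.0% on day 10, 43.1% on day 20 and 49.4% on day 30. Across the peaks of a list, the signals of the 2 libraries were correlated with Spearman's rho of 0.939 in satellite cells, 0.840 in myoblasts, and 0.928, 0.977 and 0.816 on days 10, 20 and 30. Peaks are not independent replicates, and list length depends on depth and on agreement between the libraries as well as on the cells.

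Satellite cells and myoblasts shared most of the satellite cell landscape. Of the satellite cell regions 76.5% were also called in myoblasts, whereas 45.4% of the myoblast regions were called in satellite cells. There were 7344 satellite-cell-only, 28660 myoblast-only and 23865 shared regions. Of the shared regions 45.3% (44.7 to 45.9) touched a gene boundary, against 9.38% (8.72 to 10.1) of satellite-cell-only and 7.42% (7.12 to 7.73) of myoblast-only regions. Peaks were placed by their summit, a narrower measure than the overlap of a whole region used for the classes. By summit, the percentage of peaks at a gene boundary was 32.9% in satellite cells and 21.5% in myoblasts. It was 25.2%, 21.2% and 27.6% on days 10, 20 and 30. When every list was shortened to 32109 peaks by score, these percentages lay between 31.0% and 32.9%.

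The genes with the largest satellite cell excess were led by Zbtb16, a zinc finger transcription factor on chromosome 9 (48651797 to 48836225, mm10), with 19 satellite-cell-only regions and 0 myoblast-only regions. Rora, a nuclear receptor, had 18 and 1, Pdzd2 had 17 and 0, and Hmcn2, which encodes a hemicentin of the extracellular matrix, had 16 and 3. Tgfbr3, the betaglycan co-receptor of TGF-β, had 12 and 0. Tshz2 had 12 and 0, Fry 13 and 2, Clmn 11 and 0, Camta1 16 and 6, and Prkce, a protein kinase C, 13 and 3. The largest myoblast excess was at Dlg2, with 28 myoblast-only and 2 satellite-cell-only regions. Sorcs2 followed with 27 and 2, and Tns3, which encodes a tensin of focal adhesions, with 24 and 1. Ephb2, an ephrin receptor, had 23 and 0, and Maml3, a co-activator of Notch signalling, had 20 and 0. Atxn1 and Fhod3 had 20 and 0 each, Asic2 21 and 1, Agap1 24 and 5, and Rptor, a component of the mTORC1 complex, 21 and 2. With lists of equal length the myoblast excess of these 10 genes was smaller by over 1.5 times in each case and that of Agap1 was 1 region by score, while each of the 10 satellite cell genes had an excess of at least 11 regions.

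At the genes fixed beforehand, Calcr, the calcitonin receptor of quiescent satellite cells, had a region at its boundary (chromosome 6, 3763203 to 3764808) that was called in satellite cells and in none of the other lists. Cd34, a surface marker of quiescent satellite cells, had 5 satellite-cell-only regions and 1 myoblast-only region. The quiescence gene Spry1 had 1 of each. Of the myogenic factors, Myf5 had 1 satellite-cell-only region (chromosome 10, 107487929 to 107489588), Myf6 had 2, and Myod1 had none of either kind. Myog, which drives terminal differentiation, had 0 satellite-cell-only and 3 myoblast-only regions, and Pax3 had 0 and 3. The Notch target Hes1 had 1 and 7, a difference that turned round to 1 more satellite-cell-only region with a global IDR of at most 0.01, while Hey1 and Heyl had 0 of either. At Pax7, 15 of 17 regions were shared, but peaks there covered 50.4% to 88.2% of a 200 kb window in the 5 lists, which is described with the additional observations. Pax7 accessibility was therefore not compared on its own. Its 17 regions, with 0 satellite-cell-only and 2 myoblast-only, stayed in the counts of the quiescence and myogenic regulator lists. These lists were not computed without Pax7.

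**Figure D1:**
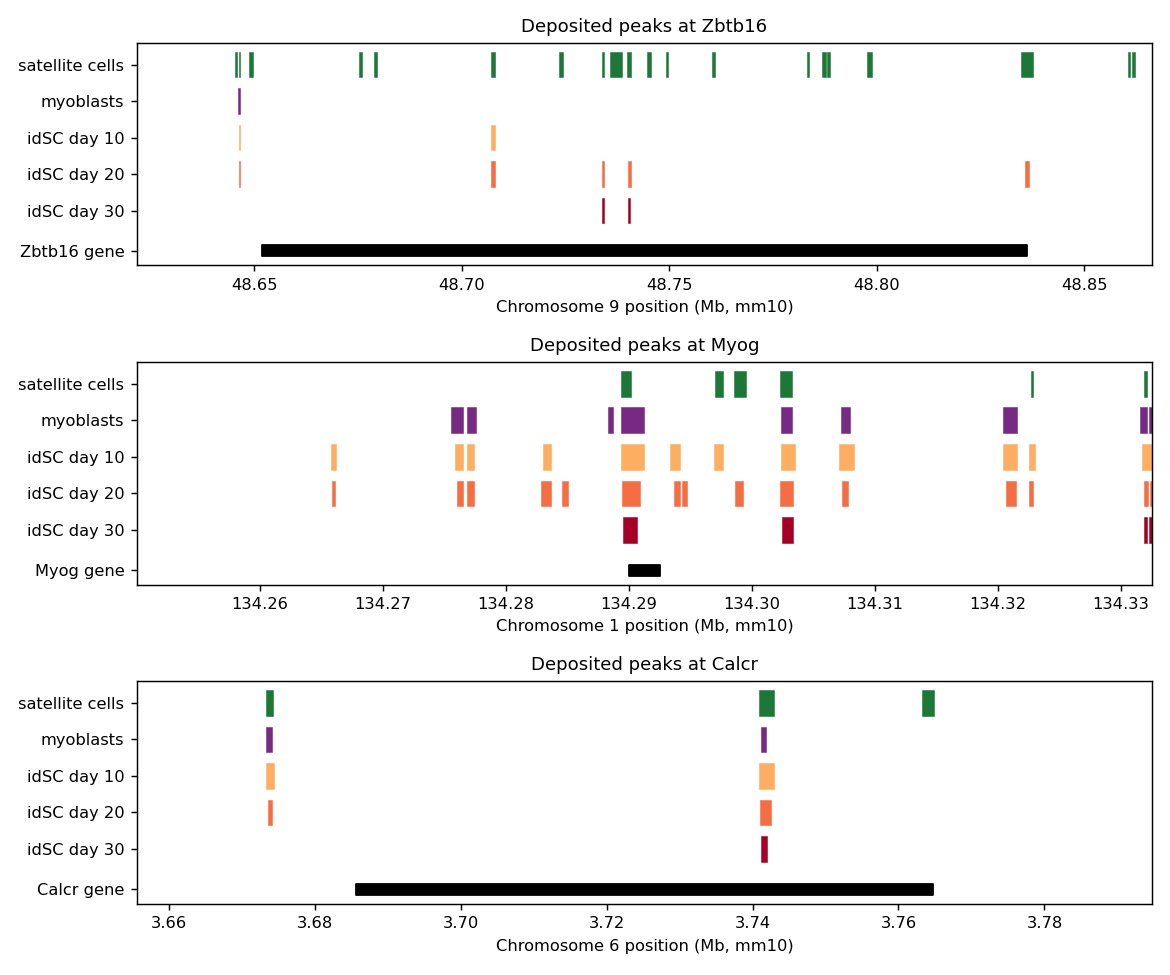
Deposited peaks (coloured bars, 1 row per list) along chromosome position in Mb (mm10) at Zbtb16, Myog and Calcr, with the annotated gene as a black bar. Zbtb16 carried 20 regions in satellite cells and 1 in myoblasts, regions assigned to Myog numbered 8 on day 20 and 1 on day 30, and the region at the right-hand end of Calcr was called in satellite cells alone.

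Among the 23 gene lists, satellite cell quiescence stood highest: its genes had 70 satellite-cell-only and 98 myoblast-only regions, a log2 ratio of -0.48 against a median of -1.91 for matched random lists (percentile 99.95). The excess came from part of the list. Of its 32 members, 12 had more satellite-cell-only regions, among them Chrdl2, a BMP antagonist, with 8 and 0, while 15 had more myoblast-only regions, among them Megf10 with 0 and 10, Cebpb with 0 and 7 and Col5a1 with 6 and 13. The boundaries of Calcr, Chrdl2, Dio2 and Tek were called in satellite cells and not in myoblasts, and that of Lifr the other way round. The TGF-β and BMP pathway had 43 and 67 regions (percentile 99.2), with Tgfbr3 at 12 and 0, Bmp2 and Bmp4 at 3 and 0 each, and Ltbp1 at 4 and 14. The interferon and MHC class I list had 6 and 3 (percentile 99.1), with Ifit1 and Isg15 called at their boundaries in satellite cells only of these 2 groups.

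Marker lists of other muscle-resident cells were measured in the same way because the sorted cells could hold some of them. The fibro-adipogenic list had 21 satellite-cell-only and 27 myoblast-only regions (percentile 98.6), with Dpt at 7 and 2, Cxcl14 at 3 and 0 and Twist2 at 0 and 5. The glial list had 6 and 4 (percentile 98.7), with 5 of the 6 at Ngfr and the other at Plp1. The haematopoietic list had 0 and 22 (percentile 0.79), with Laptm5 at 0 and 7, Fcgr3 and Itgam at 0 and 3 each. Endothelial genes had 12 and 31 (percentile 81.5), with Erg at 5 and 0 and Cdh5 at 1 and 8. Mural genes had 2 and 8 (percentile 70.8; 98.7 with lists of equal length by score) and tenocyte genes 2 and 3 (percentile 89.2). The haematopoietic percentile was 17.4 and the fibro-adipogenic percentile 95.6 with lists of equal length by score, and that of the TGF-β and BMP list was 85.4, while the interferon, glial and TGF-β and BMP lists were at 92.2, 91.7 and 96.7 with a global IDR of at most 0.01.

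Muscle differentiation genes leaned to myoblasts without leaving the range of random lists as deposited. They had 6 satellite-cell-only and 65 myoblast-only regions (percentile 3.59; 0.875 with a global IDR of at most 0.01, and 1.775 and 0.145 with lists of equal length by score and by signal), and 21 of 31 members had more myoblast-only regions. The boundaries of 18 were called in satellite cells and of 26 in myoblasts, with Actc1, the cardiac actin of embryonic muscle, Myh3, the embryonic myosin, Ttn and Mymk, the myoblast fusion factor myomaker, among those called in myoblasts alone of these groups and Myh2, an adult fast myosin, the other way round (Actc1, Ttn and Mymk were chosen after their values were seen). The Notch list had 6 and 60 (percentile 4.54), led by Notch2 and Dll1 with 10 and 8 myoblast-only regions. Housekeeping genes had 0 and 15 (percentile 4.63), 9 of them at Ywhaz.

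The other lists lay inside the range of random lists. Hox genes had 10 and 18 (percentile 97.1), with the boundaries of Hoxa5, Hoxd3, Hoxd8 and Hoxd9 called in satellite cells and not in myoblasts and that of Hoxc12 in the reverse. The immediate early list had 24 and 49 (percentile 94.4) and the presomitic mesoderm list 15 and 31 (percentile 90.3), with Lbx1 at 5 and 0, Cxcr4 at 5 and 1, Met at 0 and 11 and Meox1 at 0 and 9. Circadian genes had 10 and 27 (percentile 77.3), pluripotency genes 8 and 23 (percentile 69.4), myogenic regulators 17 and 60 (percentile 64.7) with Eya4 at 1 and 16, and extracellular matrix genes 34 and 123 (percentile 55.1) with Col4a2 at 3 and 15. Wnt genes had 14 and 74 (percentile 28.9) with Tcf7l2 at 1 and 18, cell cycle inhibitors 3 and 20 (percentile 27.8), cell cycle genes 5 and 35 (percentile 16.9), and hypoxia and glycolysis genes 6 and 45 (percentile 15.2; 1.57 with lists of equal length by score) with Egln3 at 0 and 9. In all, 6 of the 23 lists lay outside the central 95% of random lists, where chance gives 1.15. The number was 3 with a global IDR of at most 0.01, and 8 with lists of equal length by signal or with assignment within 50 kb. It was 6 with lists of equal length by score or without chromosomes 6, 14, X and Y.

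**Figure D2:**
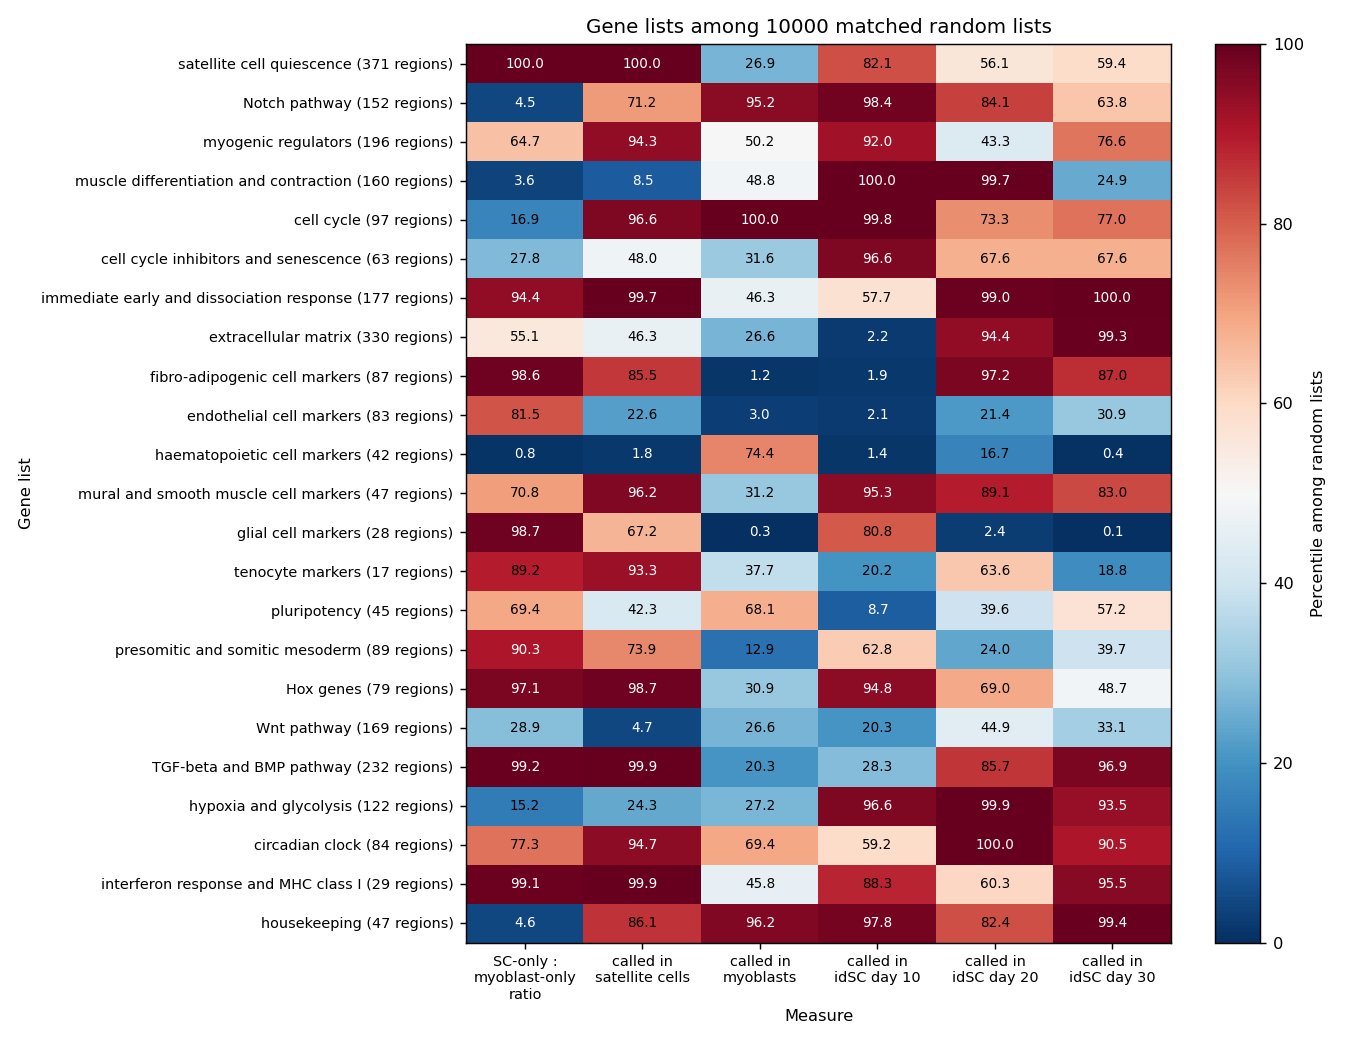
Percentile of each gene list (rows, with its number of union regions) among 10000 random lists matched on regions per gene, for the ratio of satellite-cell-only to myoblast-only regions and for the percentage of regions called in each group (columns). Satellite cell quiescence lies at 99.95 for the ratio, and muscle differentiation at 100 on day 10, 99.7 on day 20 and 24.9 on day 30.

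Whether idSC lists held satellite cell regions that the myoblast list lacked was examined at the 7344 satellite-cell-only regions. Their absence from the myoblast list is by definition, so a call in another list is not by itself a regained region. No second myoblast list was available as a baseline. On day 10, 36.2% of the satellite-cell-only regions were called (35.1 to 37.3), on day 20 41.3% (40.2 to 42.4) and on day 30 15.5% (14.6 to 16.3). In all, 52.6% (51.4 to 53.7) were called on at least 1 day and 681 regions, or 9.27% (8.62 to 9.96), on all 3 days. Over the 19 autosomes the shares ran from 28.4% to 42.2% on day 10, 31.2% to 47.3% on day 20 and 9.93% to 20.9% on day 30. Chromosome 6 gave the highest share on day 10 and the lowest on day 20, and chromosome 14 the lowest on day 30. Signal on both chromosomes also differed between libraries, as described below. Day 30 was lower than day 20 and day 10 on each of the 19 autosomes. The order of days 10 and 20 depended on list length. With every list at 32109 peaks by score, the class was defined anew and held 11678 regions, of which 33.8% were called on day 10, 25.4% on day 20 and 20.4% on day 30 (3951, 2969 and 2382 regions). With a global IDR of at most 0.01 it held 4847 regions, and the shares were 50.2%, 35.8% and 6.04%.

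Prox1, a homeobox transcription factor (chromosome 1, 190118035 to 190170827), had 11 satellite-cell-only regions, of which 8 were called on day 10, 6 on day 20 and 0 on day 30. Rad51b, a gene of homologous recombination, had 11, with 8, 5 and 2 called on these days, and the transcription factor gene Nfia had 14, with 5, 7 and 1. Camta1 had 16, with 1, 8 and 3 called, Rora 18, with 2, 7 and 4, and Errfi1, an inhibitor of EGF receptor signalling, 10, with 3, 7 and 4. Zbtb20, Tcf4, Arid1b and Plekha6 completed the 10 genes with most such regions, with 7 each called on some day. At Zbtb16, 4 of the 19 satellite-cell-only regions were called on any day. The satellite-cell-only region at Spry1 (chromosome 3, 37666408 to 37668038, outside the gene) was called on all 3 days, that at Myf5 on day 10 alone of the 3, and that at the Calcr boundary on none. Of 5 such regions at Cd34, 2 were called on day 10, 2 on day 20 and 1 on day 30. For the quiescence list 29 of 70 satellite-cell-only regions were called on day 10, 27 on day 20 and 13 on day 30, percentages of 41.4, 38.6 and 18.6 that lay at percentiles 71.0, 29.4 and 66.5 of random lists.

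**Figure D3:**
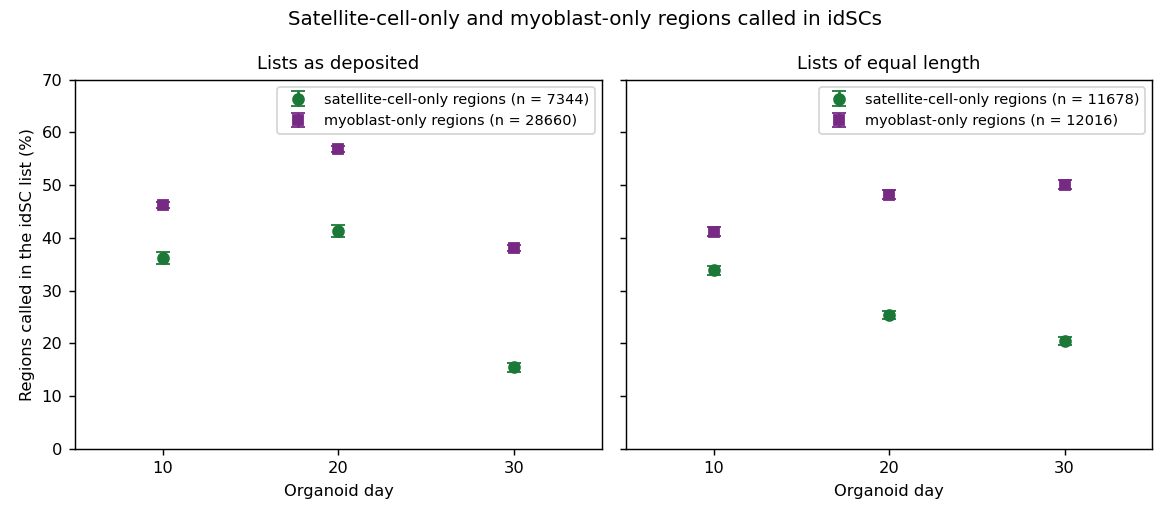
Percentage of satellite-cell-only (circles) and myoblast-only (squares) regions called in the idSC list of each organoid day, with exact 95% intervals as bars, for the lists as deposited (left) and for lists shortened to 32109 peaks by score (right). Satellite-cell-only shares were 36.2%, 41.3% and 15.5% as deposited and 33.8%, 25.4% and 20.4% at equal length, where myoblast-only shares were 41.2%, 48.2% and 50.1%.

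Regions of the myoblast state were called more often than satellite-cell-only regions on every day. Of the 28660 myoblast-only regions 46.3% (45.7 to 46.9) were called on day 10, 56.8% (56.2 to 57.4) on day 20 and 38.0% (37.4 to 38.6) on day 30. Shared regions were called at 96.6%, 96.6% and 84.9%. The share of satellite-cell-only regions divided by that of myoblast-only regions was 0.782 on day 10, 0.727 on day 20 and 0.407 on day 30. At equal length by score this quotient was 0.821, 0.528 and 0.407. The place of day 30 among the myoblast-only shares depended on the list length: at equal length by score day 30 was at 50.1%, above the 41.2% of day 10 and the 48.2% of day 20, whereas with a global IDR of at most 0.01 it was 19.6%.

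Dlg2, Nav2 and Ephb2 each had 20 myoblast-only regions that were not called on day 30, out of 28, 26 and 23. Ptprt, a receptor tyrosine phosphatase, had 19 myoblast-only regions, of which 4 were called on day 10, 1 on day 20 and 0 on day 30. Prex1, an exchange factor for Rac, had 18, with 5, 3 and 0 called. Gse1 and Sorcs2 lacked 18 each on day 30, and Cdh13, Ulk4 and Asic2 16 each. Tns3, by contrast, had 17 of its 24 called on day 30. Muscle differentiation genes had higher shares than random lists on 2 of the days: 80.0% of their 65 myoblast-only regions were called on day 10 and 89.2% on day 20, both at percentile 100 of random lists, and 49.2% on day 30 (percentile 92.7).

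Counting all regions, muscle differentiation genes had 83.8% of their 160 regions called on day 10 (percentile 100), 83.1% on day 20 (percentile 99.7) and 46.2% on day 30 (percentile 24.9; 62.2 with lists of equal length by score). With a global IDR of at most 0.01 the percentiles were 98.5, 74.5 and 0.025. Of the boundaries of these genes, 26 were called on day 10, 27 on day 20 and 21 on day 30. Myog had 6 regions on day 10, 8 on day 20 and 1 on day 30, against 1 in satellite cells and 4 in myoblasts; the region called in every list overlapped the gene (chromosome 1, 134289389 to 134291231). Tnni1, a slow troponin, had 11, 11 and 7 regions, Mymk 4, 4 and 0, and Actc1 4, 4 and 1. Mstn, which encodes myostatin, an inhibitor of muscle growth, had 3 regions on day 10 and 0 on days 20 and 30. Notch genes stood at percentile 98.4 on day 10 (96.6 with a global IDR of at most 0.01), 84.1 on day 20 and 63.8 on day 30, and Hes1 had 8, 14 and 10 regions.

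By overlap in base pairs, each idSC list was closer to myoblasts than to satellite cells. The Jaccard index with myoblasts was 0.602 on day 10, 0.594 on day 20 and 0.538 on day 30, and with satellite cells it was 0.497, 0.482 and 0.462. Satellite cells and myoblasts had 0.418. Shifted lists gave medians of 0.00763 to 0.0109. The closest lists were those of days 20 and 30, with 0.648. With lists of equal length by score each idSC list was again closer to myoblasts (0.603, 0.608 and 0.567) than to satellite cells (0.528, 0.518 and 0.463), and satellite cells and myoblasts had 0.454.

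Regions outside both references made up 13.8% (13.5 to 14.1) of the day 10 regions, 20.4% (20.0 to 20.7) of day 20 and 12.3% of day 30 (4548 of 36851 regions). Of these, 828 were called on all 3 days and 6.04% (4.51 to 7.88) of the 828 touched a gene boundary. Msi2, which encodes the RNA-binding protein Musashi 2, had 4. Lpp, Tcf4, Pknox2, Sorbs1, Enpp3 and Zfp36l1, a factor of mRNA decay, had 3 each, and Hivep3, Fggy and the histone deacetylase gene Hdac4 had 2 each. Enpp3 had 0 regions in satellite cells, 1 in myoblasts and 3, 8 and 5 on days 10, 20 and 30, and its boundary was called on the 3 organoid days alone. The number of such regions was 169 with a global IDR of at most 0.01 and 1317 with a reciprocal overlap of 50%.

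**Figure D4:**
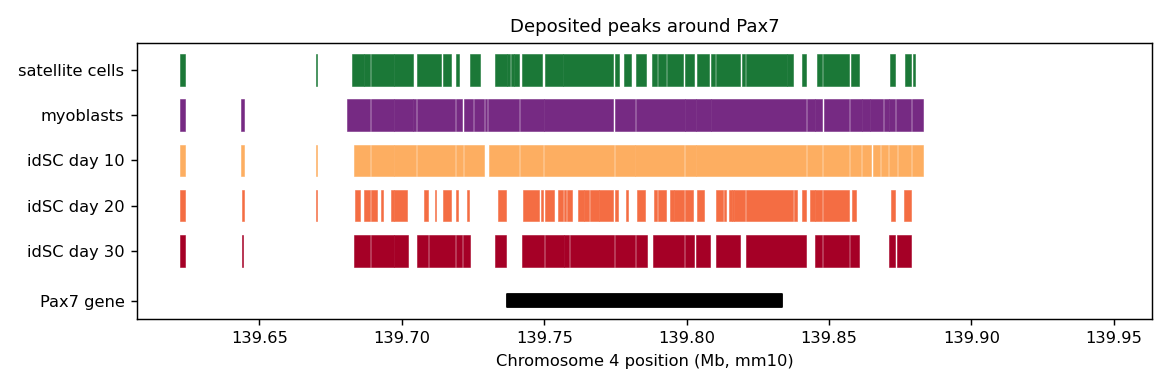
Deposited peaks (coloured bars, 1 row per list) around Pax7 along chromosome 4 in Mb (mm10), with the annotated gene as a black bar. The best 200 kb window over the gene was covered by peaks to 66.0% in satellite cells, 88.2% in myoblasts and 88.0%, 50.4% and 68.6% on days 10, 20 and 30.

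**Figure D5:**
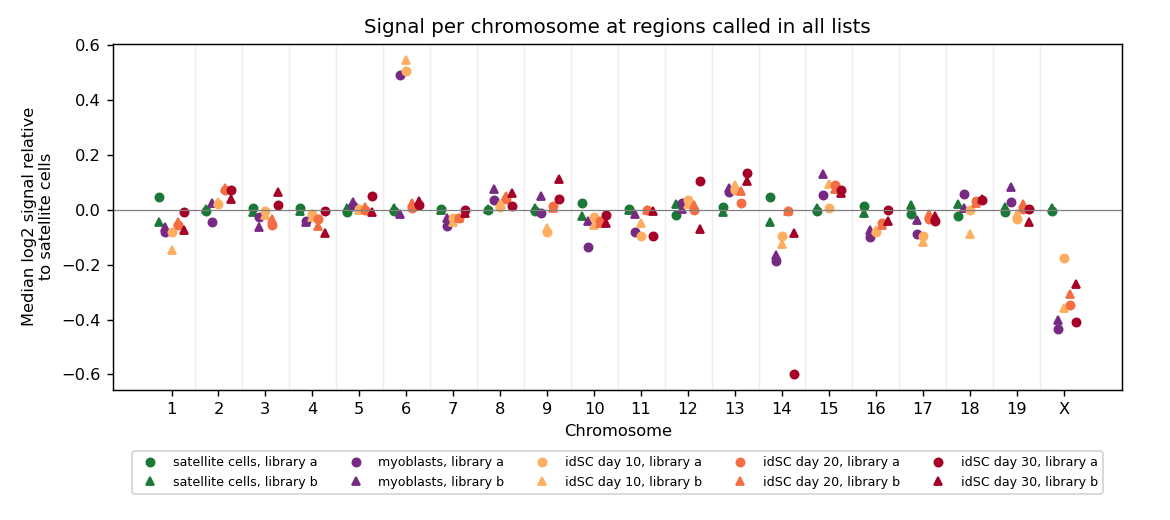
Median log2 signal per chromosome at regions called in all 5 lists, relative to the mean of the satellite cell libraries and to the autosomes of the same library, for each library (circles, library a; triangles, library b). Chromosome 6 lies at 0.49 in 1 myoblast library and at 0.50 and 0.55 in the day 10 libraries, chromosome 14 at -0.60 in 1 day 30 library, and chromosome X between -0.43 and -0.17 in all 8 cultured libraries.

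The groups also differed on whole chromosomes, as signal at regions called in all 5 lists showed. Chromosome 6 was at 0.49 on the log2 scale relative to satellite cells in 1 myoblast library and at -0.02 in the other, and at 0.50 and 0.55 in the day 10 libraries, while days 20 and 30 lay within 0.03 of 0. Chromosome 14 was at -0.60 in 1 day 30 library and at -0.08 in the other. It was also at -0.19 and -0.16 in the myoblast libraries and at -0.10 and -0.12 in those of day 10. Autosomes other than 6 and 14 lay between -0.15 and 0.13 in the 8 cultured libraries. Chromosome X lay between -0.43 and -0.17 in all 8 cultured libraries. All of chromosome Y held 3 peaks in satellite cells, 6 in myoblasts and 6, 7 and 5 on days 10, 20 and 30. Its first 2 Mb held 0 peaks in satellite cells, 4 in myoblasts and 6, 6 and 5 on these days. Peaks at Eif2s3y, Uty and Ddx3y were called in every cultured list. No list had a peak at Xist, the X-linked RNA of females, but a missing call does not tell the sex of the donors. The animals were of either sex, and the sex behind each library is not known here. A difference in donor sex between satellite cells and the cultured groups can therefore not be told apart from a difference between the cells. Without chromosomes 6, 14, X and Y the satellite-cell-only shares were 35.7% on day 10, 41.8% on day 20 and 1062 of 6648 regions on day 30.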

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

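Of the tests in this part, the coverage of the regions beside Pax7, the comparison of edges in 10 kb bins, the comparison of chromosomes among peaks of the same strength, the shares at equal length by signal and those of the strongest 25% of regions were chosen after the result was seen. The ratio between the 2 libraries of a list, outside the calls on which the comparisons of lists rest, was computed for each of 20 chromosomes and over the Pax7 block in each list, and 4 values stood over 5 robust SDs from the other chromosomes or beyond 1 on the log2 scale for the block. They were the log2 ratio of library b to library a, relative to the list, of -0.46 on chromosome 6 in myoblasts, 0.39 on chromosome 14 on day 30, -0.21 on chromosome X on day 10 (with 13 of 13 bins of 10 Mb on the same side) and -2.90 over the Pax7 block on day 30.

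Peaks covered the Pax7 locus densely in all 5 lists, from 50.4% of a 200 kb window on day 20 to 88.2% in myoblasts, where the block spanned 202 kb (chromosome 4, 139680775 to 139882832). Among all 200 kb windows of the genome, one over Pax7 had rank 1 for covered length in every list, with extra copies of the Pax7-nGFP transgene as a candidate explanation, while the next window, at Malat1 and Neat1, was covered to at most 39.1%. A wide active domain as at other myogenic genes was argued against, since windows over Myod1, Myf5 and Spry1 were covered to at most 13.8%, and so were peaks widened in general, since the 200 kb on either side were covered to at most 16.2%. That highest value, to the left on day 20, was measured from a block start at 139733835 and took in peaks of the block itself. In the other lists the highest was 10.9%, to the left in myoblasts. The edges differed by 53.1 kb on the left and 23.6 kb on the right, which had been set beforehand to count against transgene copies, but the rule ended a block at any gap over 10 kb, and gaps of up to 11.1, 12.2 and 10.6 kb lay inside it in satellite cells and on days 20 and 30, with further peaks beyond them; in 10 kb bins, a measure chosen and adjusted once after the edges were seen, the first bin was the same in all lists and the last differed by 10 kb. Copy number itself was not measured, an unusually wide domain of Pax7 alone stays open and untested, and the libraries of day 30 differed 7.45-fold over the block relative to their list.

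On chromosome 6 in myoblasts, 100% of the 10 Mb bins lay on the same side of the list median, and on chromosome 14 on day 30 it was 90%, with bins from -0.05 to 0.79. A general difference in depth or signal-to-noise that follows peak strength was argued against, since in each of 5 classes of peak strength both chromosomes lay outside the range of the other autosomes, with the smallest offsets at -0.30 and 0.18. A chromosome copy number that differed between the cultures of a group may explain both, the second less evenly along the chromosome. Chromosome X on day 10, with 100% of its bins on the same side, was not compared among peaks of the same strength, and its explanation was not tested. Copy number was not measured, and the design names no biological difference between the libraries of a group, so that no biological explanation was tested.

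The share of satellite-cell-only regions called was lowest on day 30. A shorter list alone was argued against, since at equal length by signal the share was 20.3% on day 30 and 32.1% on day 10. Those shares are of a wider class of 11606 regions, against 7344 as deposited. The satellite cell list stayed whole while the myoblast list was shortened, so part of that class was called in myoblasts as deposited. Among the 25% of regions strongest in satellite cells it was 21.6% on day 30 and 47.8% on day 10. This argued against a loss only of regions weak in satellite cells. Strength in the idSC libraries was not used, so a loss of peaks weak in idSCs was not tested. Lower agreement between the day 30 libraries, with rho of 0.816, stays open, as does the change to differentiation medium on day 20, which was not tested apart from time in culture. The labels do not say whether the organoids of the different days were seeded from the same myoblasts. Chromosome 6 signal differed between day 10 and the later days. A difference between cultures can therefore not be told apart from organoid day.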

How the results depend on the processing

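Equal length by signal, a global IDR of at most 0.05, the strongest 25% of regions and leaving out chromosomes 6, 14, X and Y were chosen after the data were seen, and the other alternatives before the data were examined. No paired analysis was possible because the calls compared come from no test, with 1 joint list per group over both libraries, and for the same reason no library could be left out. The 3 alternatives for motifs were not run, since no genome sequence was used here. The region classes were defined anew under alternatives that change the lists or the overlap, so that their sizes differ. Shares follow as satellite-cell-only on days 10, 20 and 30, then myoblast-only on these days, where they moved outside their 95% interval. With a global IDR of at most 0.01 they were 50.2%, 35.8%, 6.04%, 53.2%, 52.3% and 19.6%, and with at most 0.05 they were 43.4%, 22.6%, 10.1%, 49.4%, 40.3% and 29.7%. At equal length by score they were 33.8%, 25.4%, 20.4%, 41.2%, 48.2% and 50.1%, and by signal 32.1%, 23.8%, 20.3%, 44.2%, 50.1% and 50.4%. With a reciprocal overlap of 50% they were 33.9% on day 10 and 21.3% on day 30 for satellite-cell-only and 44.2%, 51.6% and 35.1% for myoblast-only regions. With summits within 250 bp they were 21.0% for satellite-cell-only on day 30, and 43.1%, 53.1% and 35.9% for myoblast-only. The strongest 25% of regions gave 47.8%, 54.0%, 21.6%, 71.5%, 82.99% and 65.9%. Away from gene boundaries the myoblast-only share was 44.9% on day 10, and without chromosomes 6, 14, X and Y it was 57.5% on day 20 and 39.0% on day 30. Regions called on all 3 days in neither reference numbered 169 and 296 at the IDR limits of 0.01 and 0.05 and 1317 with reciprocal overlap. Peaks in satellite cells, myoblasts and on days 10, 20 and 30 numbered 18413, 22069, 24742, 22698 and 12520 with a global IDR of at most 0.01, and 28433, 29413, 23686 and 18625 from myoblasts on with at most 0.05. The Jaccard index with satellite cells was 0.541 on day 20 and 0.5003 on day 30 and that with myoblasts 0.620 on day 20 at 0.01; at equal length by score it was 0.518 (day 20, satellite cells) and 0.567 (day 30, myoblasts), and by signal 0.518 (day 20, satellite cells), 0.614 and 0.564 (days 20 and 30, myoblasts). In windows around summits it was 0.356, 0.331 and 0.325 with satellite cells and 0.411, 0.427 and 0.378 with myoblasts, lower by construction. Windows of 2500 bp put 39.8%, 28.6%, 32.3%, 27.9% and 34.3% of the peaks of the 5 lists at gene boundaries, more by construction, and equal length gave 31.0%, 32.7%, 31.5% and 31.0% from myoblasts on. Gene lists outside the central range numbered 3 with a global IDR of at most 0.01, against 6 as deposited. The difference of satellite-cell-only and myoblast-only regions at Hes1 turned from 1 against 7 as deposited to an excess of 1 satellite-cell-only region at 0.01. Except where stated, the cause was not tested. Under every alternative run for the shares, day 30 had the lowest satellite-cell-only share. The other 45 values of this kind stayed within their limits. Of 690 percentiles of gene lists under the alternatives, 602 stayed on their side of the limits, 46 came inside and 42 went outside. Of 159 differences at named genes, 99 stayed within 1.5 times, 59 moved further and 1 changed sign. Sequencing depth was unknown, so its part in the length of the lists was not measured, and a region that was not called is not shown to be closed.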

Other observations

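Gene lists also differed in the percentage of their regions called, and some lay outside the central 95% of matched random lists. Cell cycle genes had 87.6% of their regions called in myoblasts and 79.4% on day 10 (percentiles 100 and 99.8; day 10 at 96.4 with lists of equal length by score), and 55.7% on day 30 (percentile 77.0). Immediate early genes, which respond to tissue dissociation, had 54.2% in the freshly sorted satellite cells (percentile 99.7, and 94.95 with lists of equal length by score). They had 81.4% on day 20 and 68.4% on day 30 (percentiles 99.05 and 100). In cultured myoblasts they had 68.4% (percentile 46.3) and on day 10 60.5% (percentile 57.7). The percentage itself was thus not highest in the freshly sorted cells. Hypoxia and glycolysis genes had 86.1% on day 20 (percentile 99.9), and circadian genes 88.1% (percentile 100; 97.2 with a global IDR of at most 0.01 and 96.3 at equal length by signal). Extracellular matrix genes had 50.9% on day 10 (percentile 2.24; 4.755 to 22.4 under the 5 alternatives, inside the range) and 55.8% on day 30 (percentile 99.3; 55.5 with a global IDR of at most 0.01). Fibro-adipogenic genes had 55.2% in myoblasts (percentile 1.22). Glial genes had 42.9% in myoblasts (percentile 0.28) and 21.4% on day 30 (percentile 0.135; 9.95 with a global IDR of at most 0.01 and 3.425 at equal length by score). Housekeeping genes had 80.9% on day 10 and 72.3% on day 30 (percentiles 97.8 and 99.4; 93.6 and 94.1 with lists of equal length by score). Quiescence genes stood at percentile 100 in satellite cells and at 82.1, 56.1 and 59.4 on days 10, 20 and 30.

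Between successive lists, 8899 regions were called on day 10 and not in myoblasts, and 29.9% of these were satellite cell regions. Of 75178 union regions, 52525 were called in myoblasts, and 7344 of the others were satellite cell regions. The 29.9% was not above the share among all regions outside the myoblast list. That share, however, includes 3483 regions called in satellite cells alone, which are in the union only through that list. The comparison therefore cannot tell whether the day 10 regions favoured satellite cell regions, and no conclusion is drawn from it. From day 20, 18614 regions were not called on day 30, and 25.8% of these were satellite cell regions. That was below the whole day 20 list, where 43.3% of regions were shared and 5.70% satellite-cell-only. On day 30, 2262 regions were called that were not called on day 20, 6.06% of them in satellite cells. Kdm5d had no peak in any list, while Uty had 2, 1, 2 and 2 peaks in myoblasts and on days 10, 20 and 30. Peaks on chromosome 6 made up 6.30% of the myoblast list, 6.94% of day 10 and 5.07% of satellite cells.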
